A study of Homo sapiens with 98 samples.

How the data were processed

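Gene expression was measured on 98 single-colour Affymetrix oligonucleotide arrays, each hybridised with RNA of 1 culture of an ovarian cancer cell line. Per the labels' protocols, 32 lines were grown untreated and harvested in exponential growth at 50 to 80% confluence, and 1 µg of total RNA was labelled per array. The labels speak of at least 3 biological repeats per line. Here 28 lines had 3 arrays, JHOS.3, OV90 and SKOV3 had 4, and OVCAR5 had 2. Lines were grouped by the name in each array's label, and no histological type was assigned to any line.

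The deposited values are normalized log2 expression values, 1 per probe set and array. Per the submitters' processing notes, the tools were GCRMA, a background correction and normalization method, and the affy package. Versions, settings and annotation were not given in the sources used here. The log base was not stated either: the deposited values lay between 1.86 and 14.9, as log2 array values do, and every difference is given on that scale. As a method, GCRMA corrects for background with the help of probe sequence and normalizes arrays together, which can compress or distort differences between dim genes. Array medians lay between 6.30 and 6.56. Arrays carry no read depth, and their number per line limits the precision.

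Of 33252 probe sets, 19460 carried 1 gene symbol in the platform annotation, 1754 carried several and 12038 were unnamed. Symbols were checked against a RefSeq gene table through Entrez identifiers, and 19429 probe sets matched it. The probe set with the highest mean over all arrays stood for each of 18417 genes, of which 769 had 2 or more probe sets. A gene was tested where its probe set exceeded the median of all values (6.40) on at least 2 arrays. That left 14684 genes and removed 3733. Where a gene was dimmer than that median in a line or in the lines compared against, its level there was near the background. The difference or range then gives no exact fold.

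One linear model with a mean per line was fitted in limma, so that all lines shared 1 estimate of the spread between repeats, with 66 residual degrees of freedom. The panel test was limma's moderated F over the 32 line means. Each line was contrasted with the unweighted mean of the other 31 lines, and all 496 pairs of lines were contrasted. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with a difference (panel: a range of line means) of at least 2 on the log2 scale, which is 4-fold. The p-values measure the spread between repeats of a line and take the lines as fixed. They do not measure the spread between tumours or patients. Similarity between arrays was Pearson's r over the tested genes.

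Gene lists were fixed before the data were examined. They covered epithelial, mesenchymal, Müllerian and serous, clear cell, gastrointestinal and mucinous, pluripotency and germ cell, cancer-testis, neural and neuroendocrine, melanocytic, leukocyte, endothelial and fibroblast genes. They also covered proliferation, cell cycle entry, p53 targets, interferon response, MHC class I and class II, DNA repair, drug transport and detoxification, Wnt targets, NRF2 targets, hypoxia and glycolysis, cholesterol synthesis, inflammatory cytokines, HOX genes and ribosomal proteins. The last 3 held neighbours of ERBB2, of CCNE1 and of CDKN2A. Of 478 list entries, 417 had a probe set of their own. The 29 lists with at least 5 tested members were tested in each line, giving 928 combinations, with limma's cameraPR at a preset correlation of 0.01 between genes. The camera test with an estimated correlation stood beside it, and both were adjusted over all combinations. The CDKN2A list had 3 members and is described gene by gene. Member counts are of genes past an adjusted p of 0.05, over all tested genes or adjusted over the list alone.

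Of 18 gene pairs fixed before the data were examined, 12 had both genes on the arrays with a probe set of their own. For these, Pearson's r and Spearman's rho were computed over line means, with two-sided permutation tests of 100000 resamples and Benjamini-Hochberg adjustment over the 18 correlations computed. The smallest p these permutations can give is 1e-05. Where a mixture model (mclust, a margin of 6 in the Bayesian information criterion) split the lines by either gene, r was computed within clusters of at least 6 lines.

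The genes named were set by a rule fixed before the data were examined. They are the 25 called genes with the largest SD of line means and, per line, the 2 called genes with the largest increase, the 1 that led the next line by most, and the 1 with the largest drop. Per list they are up to 4 members with the widest range and up to 3 with the largest shift where the list was called, and all members of the gene pairs. Genes linked to sex, including all on chromosome Y, were left out of the names. Probe sets of several genes or of none were not named. Genes with near-identical copies, such as CD24, EPCAM, the histone genes H2BC12, H1-5 and H3C11, the HLA genes, AKR1C1, SNORD116-14, OR7E19P and ZNF542P, can share probe signal with those copies and are uncertain in that respect.

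The steps were tested on simulated data before use. With 14684 genes and 50 genes changed per size in CH1 against the other 31 lines, log2 changes of 2.5 and 3.5 were called in 100% of genes, a change of -2.5 in 98%, and a change of 1 passed the adjusted p in 96% but by its size was called in 0%. No unchanged gene was called, but that was largely built in. The simulated noise was independent between genes, around 1 mean for all lines, and small against the fold threshold. It does not measure false calls in the real data. Alternatives covered the filter on dim probe sets, the probe set that stands for a gene, median centring, quantile normalization, the variance model, a replicate block, fold thresholds, the correlation coefficient, the correlation between list members, and leaving out each array in turn. Dropping probe sets with a cross-hybridisation suffix was planned but did not apply to these probe set names. Leaving out the array labelled OAW42 replicate 2 from all results was added after its profile was seen. Runs of neighbouring genes were sought with windows of 15 genes in the order of the RefSeq table, against 200 shuffled gene orders. The software was R 4.3.3, limma 3.58.1, data.table (1.17.8), mclust 6.1.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.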

Results

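Gene expression profiles were collected from 98 arrays of 32 ovarian cancer cell lines, all grown without treatment. 28 lines were represented by 3 arrays, JHOS.3, OV90 and SKOV3 by 4, and OVCAR5 by 2. The design had a single factor, the cell line, and so the comparisons asked which genes differed across the panel, what set each line apart from the others, and how alike any pair of lines was. Levels are normalized log2 values given as mean ± SD over the arrays of a line (n = 3 unless stated), and differences are log2 ± SE from the limma fit. The median SD between repeats of a line was 0.21 over the 14684 genes tested.

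Repeats of a line resembled each other far more than they resembled other lines. The median correlation between arrays was 0.987 within lines and 0.851 between lines, and 94 of 98 arrays correlated best with an array of their own line. The 4 others were the array labelled OAW42 replicate 2 and the arrays of OAW28. That array correlated with OAW28 at 0.989 to 0.993 and with OAW42 replicates 1 and 3 at only 0.859 to 0.869, whereas those replicates correlated with each other at 0.972. Every other pair of repeats reached at least 0.961, and no other pair of arrays from different lines exceeded 0.957. The array also carried the OAW28 levels of single genes, among them high keratin KRT7 and claudin CLDN6, low vimentin VIM and low HSD17B4, a peroxisomal enzyme. Values include it unless stated. It also widened the shared spread of genes that differ between OAW28 and OAW42: for 26 of 231 named differences the SE was at least 1.5 times the SE without the array, and up to 2.97 times.

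**Figure D1:**
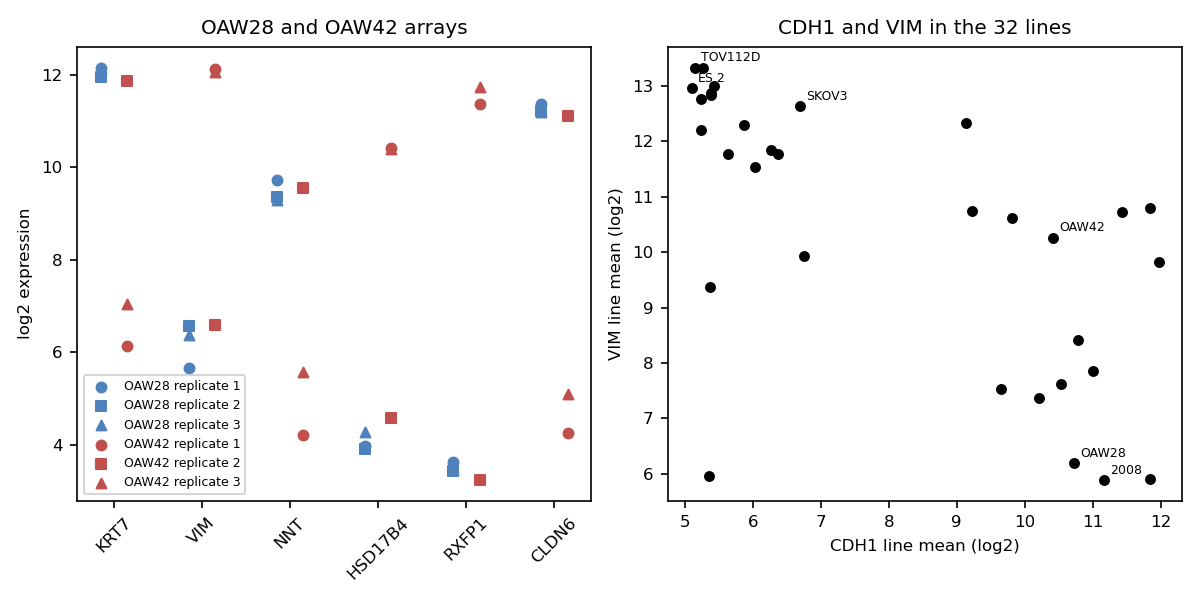
Left, log2 expression of 6 genes on each array of OAW28 (blue) and OAW42 (red), with the replicate number as the symbol; OAW42 replicate 2 lies with OAW28 for each gene. Right, line means of CDH1 and VIM on the log2 scale, 1 point per line, with the lines in a low-CDH1 and a high-CDH1 cluster.

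Across the panel, the 25 genes with the widest spread of line means included genes for secreted proteins, junction proteins and receptors. The secreted phosphoprotein SPP1 was lowest in 2008 and reached 13.82 ± 0.03 in RMG.II, a range of 8.82 (adjusted p = 7.9e-44 by limma's moderated F). The relaxin receptor RXFP1 ranged from 3.20 in 59M to 12.67 in RMG1, and the copper carrier ceruloplasmin CP was lowest in 59M and highest in RMG.II (12.85). The epithelial adhesion molecule EPCAM had a range of 9.77, from 3.47 ± 0.13 in ES.2 to 13.24 ± 0.04 in OAW28. Junction and adhesion genes in the same group of 25 were CLDN16 (range 8.37), CLDN1 (8.58) and the cadherin CDH6 (8.38). Secreted inhibitors and matrix proteins were DKK1, a Wnt antagonist (8.21), the protease inhibitor SLPI (7.72), SPARC (7.42), MFAP5 (8.28) and SPON1 (6.89). Enzymes, transporters and other products completed the group: the peptidase DPP4 (9.04), the calcium-binding protein CALB1 (9.38), the aldehyde dehydrogenase ALDH1A1 (8.94), CYP1B1 (7.16), GDA (7.19), the phosphate transporter SLC34A2 (7.89), the neuropeptide precursor NTS (9.42), the cytokine IL18 (7.53), MAL2 (8.44), HAVCR1 (7.78), PROM1 (7.35), the noncoding RNA UCA1 (8.07) and the small nucleolar RNA SNORD116-14 (8.96).

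By the panel test, 13862 genes (94.4%) passed the adjusted p and 6678 (45.5%) also had line means at least 2 apart. The count depended on the fold threshold: 12470 genes had a range of at least 1.

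Each line carried its own set of strongly expressed genes. A median of 294 genes per line was called against the other 31 lines, from 106 in OAW42 to 734 in COLO.704. Summed over lines, calls with higher levels (6926) outnumbered those with lower levels (4289). The reverse held in A2780 (255 higher and 373 lower), COLO.704 (334 and 400), Colo.720E (231 and 411) and IGROV1 (126 and 143). These counts rest on the fold threshold: by the adjusted p alone, 5168 genes passed in OAW42 and 8710 in COLO.704. Of 3502 genes called in at least 1 line, 1472 were called in exactly 1. Without the array labelled OAW42 replicate 2, OAW42 had 286 calls (180 higher and 106 lower), and the fewest were in OVCAR4 (210). Among the genes named for a line by their increase, lead or drop, the largest adjusted p was 1.06e-13 (limma, RXFP1 in IGROV1). Without that array this one was 2.6e-37. Members named for a called list could have a larger one, such as 4.18e-08 for FN1 in OVCAR4 (limma).

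**Figure D2:**
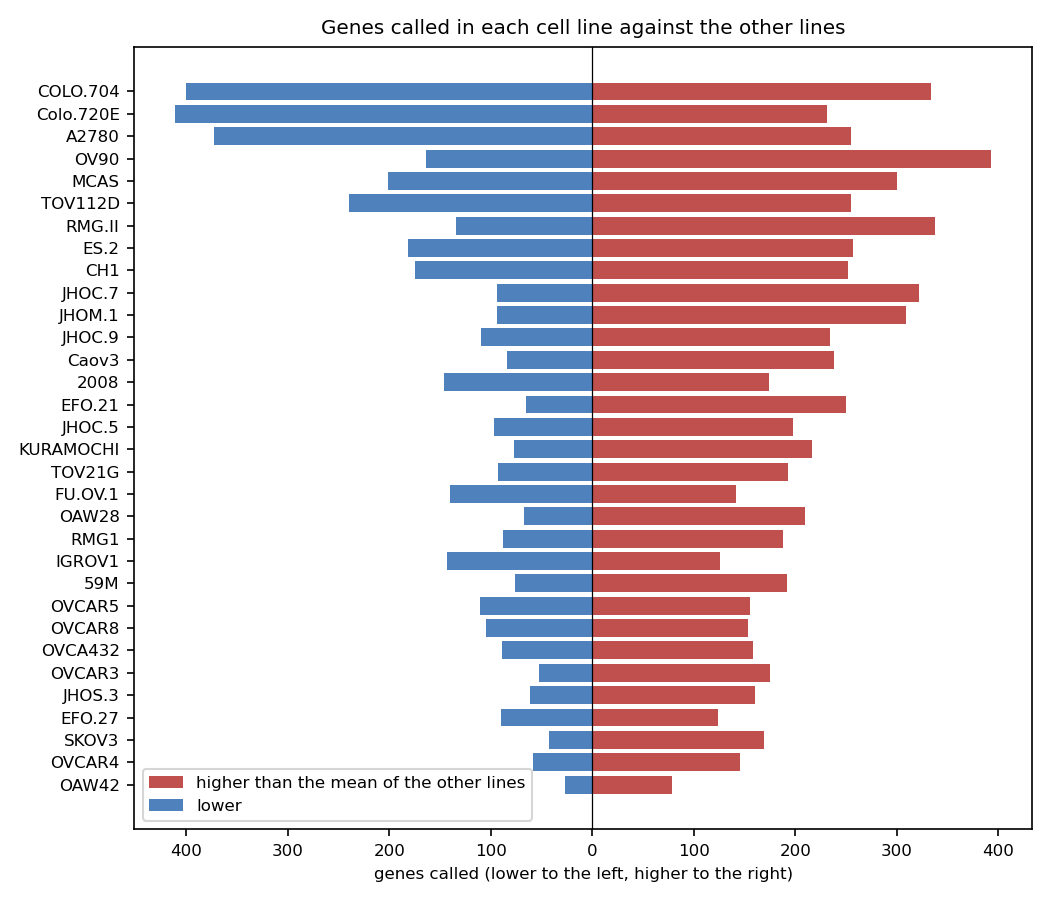
Number of genes called higher and lower in each of the 32 lines against the mean of the other 31 lines (adjusted p under 0.05 and a log2 difference of at least 2). COLO.704 had the most calls (734) and OAW42 the fewest (106). Without the array labelled OAW42 replicate 2, OAW42 had 286 and OVCAR4 the fewest (210).

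In A2780 the protease inhibitor PI15 (difference 9.11 ± 0.17) and the hepatocyte growth factor HGF (8.42 ± 0.09, adjusted p = 1.39e-73 by limma) stood far above the panel, and no other line exceeded a mean of 4.16 for HGF. In TOV112D the glucagon gene GCG was at 12.91 ± 0.27 against 4.05 in the other lines, and the protocadherin PCDH18 was higher by 7.18. CH1 had high NTS (8.31 ± 0.28), LIN28A, an RNA-binding protein of pluripotent cells (6.63 ± 0.21), and VAT1L (6.30 ± 0.15). COLO.704 was led by the serotonin-synthesis enzyme TPH1 (6.85 ± 0.16), IMPG2 (6.80 ± 0.20) and PIWIL2, a germline PIWI protein (6.12 ± 0.12). Colo.720E shared IMPG2 (6.86 ± 0.20) and had SERPINF1 (6.69 ± 0.26) and the protocadherin PCDH8 (4.59 ± 0.12). FU.OV.1 had ENPP2, the enzyme autotaxin (5.67), EPB41L3 (5.27) and the GABA receptor subunit GABRB2 (3.97).

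OV90 (n = 4) expressed lysozyme, LYZ, at 13.06 ± 0.39 against 3.82 in the other lines, and CLCA1, a product of goblet cells, with a difference of 8.66 ± 0.11. OVCAR5 (n = 2) was led by the adhesion molecule CEACAM6 (5.78 ± 0.29), the intestinal keratin KRT20 (5.57 ± 0.14) and RARRES1 (2.90 ± 0.19). CEACAM6 was at 10.42 ± 1.42 in OVCAR5, so its arrays differed widely there, which the SE shared by all lines does not show. MCAS had C6orf15 (6.21 ± 0.10), which no other line had above a mean of 6.81, and ANKRD22 (5.68 ± 0.24). Caov3 had the metalloreductase STEAP4 (8.13 ± 0.24), SPINK6 (6.27 ± 0.16) and DMBT1 (5.37 ± 0.13).

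RXFP1 and CALB1 were high together in JHOC.7 (7.02 ± 0.50 and 6.99 ± 0.29) and in JHOC.9 (7.20 ± 0.50 and 6.98 ± 0.29). JHOC.7 was further marked by the prolactin receptor PRLR (3.82) and JHOC.9 by PNMA5 (5.65). RXFP1 was also among the leading genes of RMG.II (6.93 ± 0.50), RMG1 (7.70 ± 0.50) and IGROV1 (5.01 ± 0.50). The SE of RXFP1 was 0.18 in each of these lines without the array labelled OAW42 replicate 2. RMG.II had the lymphocyte activation marker CD69 (7.22) and ERVH48-1 (6.19), RMG1 the metalloproteinase MMP7 (6.21) and the bile acid transporter SLC10A2 (5.10), and IGROV1 had ALDH1A1 (5.05) and PGM5 (3.93). The fibrinogen chain FGB was among the leading genes of JHOC.5 (6.26 ± 0.15) and TOV21G (6.23 ± 0.15), although its mean was highest in OV90 (11.93). JHOC.5 also had SERPINB7 (5.65) and LINC00221 (3.44), and TOV21G had the actin-severing protein SCIN (5.68) and the cartilage matrix protein COMP (4.10).

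Keratin genes of stratified epithelium marked 2008, with KRT13 at 13.53 ± 0.28 against 6.67 elsewhere and KRT5 higher by 6.84 ± 0.19. KRT5 (4.90 ± 0.19) also led in EFO.27, with SERPINB5 (5.48) and ADAM19 (3.82). LMO3, a LIM-domain cofactor of transcription, was high in OAW28 (7.01 ± 0.48) and OVCAR3 (5.82 ± 0.48), where the SE was 0.20 without the array labelled OAW42 replicate 2. OAW28 also had CLDN6 (5.87) and ERP27 (5.26), and OVCAR3 had ANKRD34B (5.73) and VIT (4.23). OVCAR4 had the leukocyte actin-bundling protein LCP1 (5.49), the small heat shock protein CRYAB (4.89) and the globin CYGB (4.04). JHOS.3 (n = 4) was led by cardiac actin, ACTC1 (6.22 ± 0.14), and ADAMTS5 (5.41), and KURAMOCHI by the stem cell receptor LGR5 (5.65), SULF1 (5.62) and NXPH2 (5.37). With all its arrays, OAW42 was led by CLDN16 (4.20 ± 0.18), the urothelial protein UPK1B (3.86 ± 0.22) and GLMP (2.17 ± 0.15). Without the array labelled replicate 2 these differences were 4.50 ± 0.21, 4.80 ± 0.19 and 2.69.

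ES.2 had the collagenase MMP1 (6.39 ± 0.40), ADGRL4 (6.33) and TMPRSS15 (5.76), and 59M had IL13RA2 (5.74), EDIL3 (5.48) and MSC (5.27). OVCA432 was led by the vitamin D hydroxylase CYP24A1 (6.81 ± 0.23), CLDN6 (5.70) and HTR3C (3.10). JHOM.1 had the deiodinase DIO2 (6.34), periostin, POSTN (6.24), and the growth factor EPGN (4.90). SKOV3 (n = 4) had high CALB1, AMTN (4.55) and ZNF542P (4.98). OVCAR8 had the interleukin receptor IL7R (5.47) and the olfactory receptor pseudogene OR7E19P (6.54). EFO.21 had the endothelial adhesion molecule PECAM1 (5.80 ± 0.12), CP (5.65) and SELP (3.47), which varied between its arrays (8.20 ± 1.39).

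Several lines had a low level of a gene that the other lines expressed widely. The lactate dehydrogenase subunit LDHB was at 4.94 ± 0.60 in MCAS and 5.34 ± 0.32 in OVCAR5 (n = 2), against 12.71 and 12.70 in the other lines (adjusted p = 3.39e-67 and 2.1e-59 by limma). The S100 family gene S100A10 differed by -7.35 ± 0.30 in A2780 and -7.57 ± 0.30 in Colo.720E, and annexin ANXA1 by -6.99 ± 0.17 in COLO.704. The ubiquitin-conjugating enzyme UBE2G1 was at 4.37 ± 0.16 in SKOV3 (n = 4), where no other line was below 9.98, and the kinase MAP4K5 was at 3.87 ± 0.24 in JHOS.3 (n = 4) with no other line below 8.58. Metabolic enzymes among the drops were HSD17B4 in OAW28 (-5.81 ± 0.35, with an SE of 0.12 without the array labelled OAW42 replicate 2), ECI2, an enzyme of fatty acid oxidation, in 2008 (-4.84 ± 0.13), the glutathione transferase GSTP1 in RMG1 (-5.87 ± 0.10), GNE in JHOC.5 (-4.44), the sialidase NEU1 in JHOM.1 (-4.34) and the mitochondrial transhydrogenase NNT in OAW42 (-3.32 ± 0.29, and -4.87 ± 0.16 without the array labelled replicate 2). RHOBTB3 was lowest in JHOC.7 (-6.14), RMG.II (-6.14) and IGROV1 (-5.50). EPCAM differed by -6.31 in CH1 and -6.53 in ES.2, KRT8 by -5.23 in TOV112D, and CD24 by -4.52 in 59M and -5.92 in OVCA432. The remaining largest drops were C4orf46 in Caov3 (-5.60), SPPL3 in EFO.21 (-5.12), ADGRL2 in EFO.27 (-5.29), WLS in JHOC.9 (-4.17), IL18 in KURAMOCHI (-4.29), FSTL1 in OV90 (-4.71), TUSC3 in OVCAR4 (-4.22), GOLIM4 in OVCAR8 (-5.21), and the histone genes H2BC12 in FU.OV.1 (-5.51), H1-5 in OVCAR3 (-4.53) and H3C11 in TOV21G (-4.46 ± 0.29). H3C11 was at 7.09 ± 1.99 in TOV21G, so its arrays differed widely there, which the SE shared by all lines does not show.

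**Figure D3:**
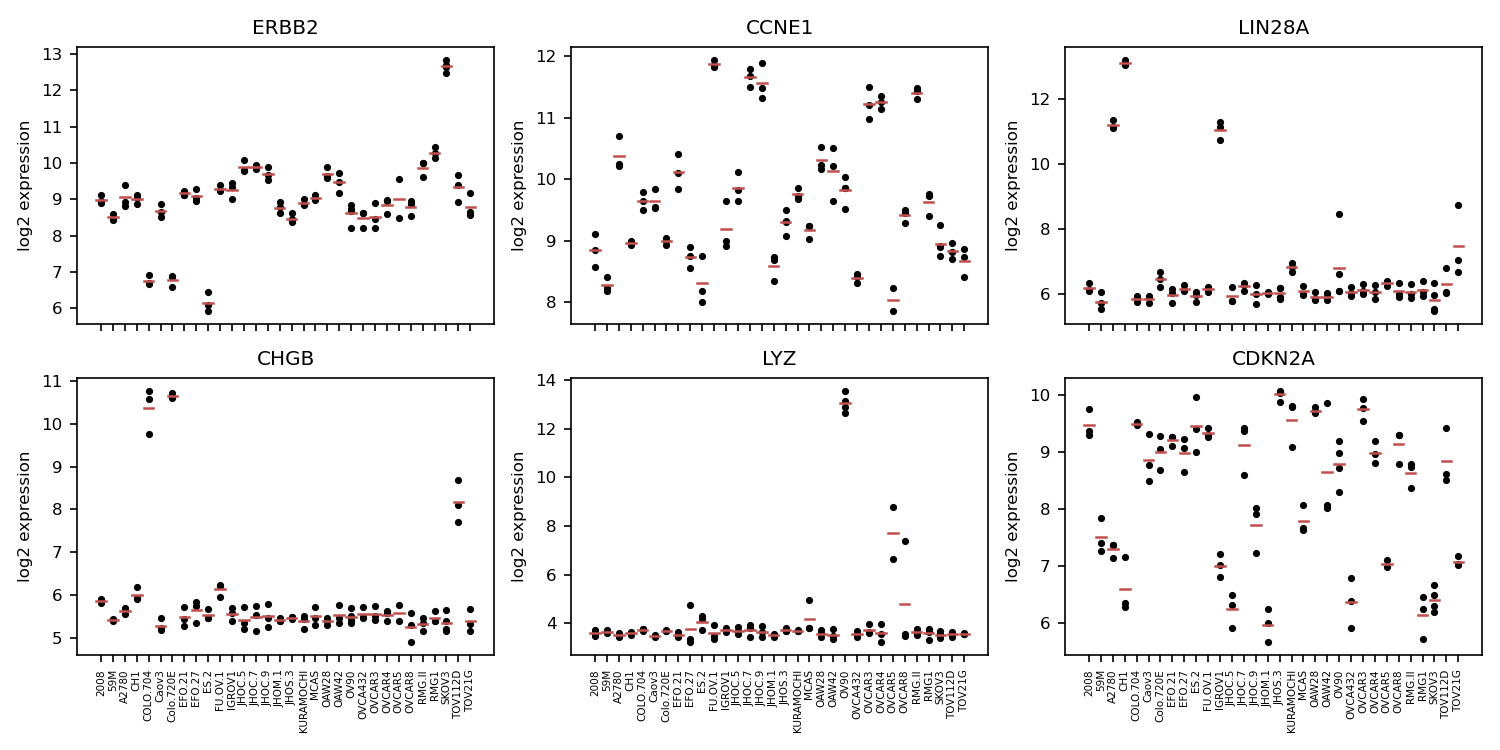
Log2 expression of ERBB2, CCNE1, LIN28A, CHGB, LYZ and CDKN2A on each array (black points), with the mean of each line as a red bar. ERBB2 was highest in SKOV3, CCNE1 in FU.OV.1, LIN28A in CH1, CHGB in Colo.720E, LYZ in OV90 and CDKN2A in JHOS.3.

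Gene lists were tested as groups in each line, which asked whether the members of a list moved together against the other genes. With the preset correlation between genes, 224 of 928 combinations of list and line were called (117 higher, 107 lower), and 38 of them (27 higher, 11 lower) also passed with the correlation estimated from the data. The member counts given below use the adjusted p alone, which many genes passed in every line. Of 14684 tested genes, 5168 in OAW42, 7697 in EFO.21 and 8710 in COLO.704 passed it, higher and lower together. A member count by itself therefore does not show enrichment, and the calls rest on the list tests.

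With all arrays kept, mesenchymal genes were the list called in the most lines (5 higher and 7 lower) with an estimated correlation. All 19 measured members differed across lines, and VIM ranged from 5.89 in 2008 to 13.34 in TOV112D and FN1, fibronectin, from 4.94 in A2780 to 13.60 in OV90 (n = 4). The list was higher in 59M, where 17 of 19 members passed upward (17 adjusted over the list alone; adjusted p = 2.2e-06 with an estimated correlation), led by COL6A3, SPARC (4.82 ± 0.25) and MMP2 (3.43 ± 0.18). It was also higher in ES.2 (16 members up, 16 adjusted over the list alone, adjusted p = 1.5e-05) with LOX (4.94) and PRRX1 (4.13), in OVCA432 (15 and 16 members, adjusted p = 9.94e-05) with TGFBI (4.10), in JHOM.1 (15 and 15 members, adjusted p = 0.011) with SNAI2 (3.49), and in SKOV3 (11 and 12 members, adjusted p = 0.0348) with AXL (2.69 ± 0.16). These adjusted p-values and the next come from limma with an estimated correlation. The list was lower in 2008 (15 members down, 15 adjusted over the list alone, adjusted p = 0.0144), JHOC.9 (14 and 15, adjusted p = 0.0195), OAW42 (11 and 12, adjusted p = 0.0203), OAW28 (14 and 15, adjusted p = 0.0218), OVCAR4 (14 and 14, adjusted p = 0.0234), IGROV1 (12 and 13, adjusted p = 0.0455) and RMG1 (14 and 14, adjusted p = 0.0455). In 2008, VIM differed by -4.65, FN1 by -4.40 and SPARC by -2.76. The N-cadherin gene CDH2 differed by -3.98 in JHOC.9 and -3.94 in IGROV1, and FBN1 by -2.26 in OVCAR4. Without the array labelled OAW42 replicate 2, the adjusted p with an estimated correlation was 0.229 in OAW42, 0.0775 in IGROV1 and 0.0531 in RMG1, so that those calls were lost. The clear cell list gained calls without that array, so the mesenchymal list no longer led alone.

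Epithelial genes varied as widely. CDH1, E-cadherin, ranged from 5.10 in ES.2 to 11.97 in JHOC.9, KRT8 from 6.98 in TOV112D to 13.64 in MCAS, and KRT19 from 6.19 in RMG.II to 12.78 in MCAS. With the preset correlation the list was higher in 14 lines, among them MCAS, where 17 of 18 members passed upward, and OAW28, where 18 did, and lower in 13, among them A2780 and TOV112D, where 18 passed downward. The correlation between members, estimated from the spread between repeats, was 0.498, and no line kept the call with it: the adjusted p was 0.121 in MCAS, 0.086 in OAW28, 0.221 in A2780 and 0.226 in TOV112D. That rested on the array labelled OAW42 replicate 2. Without it the estimated correlation was 0.288 and 6 lines were called by limma's camera: OAW28 (adjusted p = 0.00545), MCAS (0.00834), JHOC.9 (0.0141) and OVCAR4 (0.0252) higher, and A2780 (0.037) and TOV112D (0.0373) lower.

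Genes reported for clear cell carcinoma were higher in JHOC.7, where all 13 measured members passed upward (13 adjusted over the list alone; adjusted p = 0.000122 with an estimated correlation), in JHOC.9 (12 and 12 members, adjusted p = 0.00141), in RMG.II (10 and 10, adjusted p = 0.00668) and in RMG1 (9 and 9, adjusted p = 0.0249). SPP1 differed by 4.29 ± 0.38, 4.16 ± 0.38, 4.51 ± 0.38 and 3.38 ± 0.38 in these lines, and DPP4 by 5.36, 3.53, 4.31 and 3.79. The coagulation inhibitor TFPI2 was higher in JHOC.9 by 4.08 and in JHOC.7 by 3.42, and the peroxidase GPX3 in RMG.II by 3.36 and in RMG1 by 3.19. A2780 had lower levels of 10 members (10 adjusted over the list alone, adjusted p = 0.0203), with LAMB1, a laminin chain, at 5.52 ± 0.12 where no other line was below 9.44. These are limma's camera values, adjusted over all combinations. The list was also called, without the array labelled OAW42 replicate 2, as higher in OAW42 (adjusted p = 0.00175 by limma) and EFO.21 (0.0158) and as lower in TOV112D (0.0126) and COLO.704 (0.033).

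Gastrointestinal and mucinous genes were the list with the largest mean shift, 3.77, in OV90. There 14 of 17 members passed upward (14 adjusted over the list alone; adjusted p = 2.2e-06 with an estimated correlation) and 12 were called, among them TSPAN8 (8.55 ± 0.23), CEACAM6 (7.02 ± 0.21), AGR2 (7.02 ± 0.31) and TFF1, a trefoil peptide of mucous cells, at 13.56 ± 0.23. In OVCAR5 (n = 2), 9 members passed upward (9 adjusted over the list alone, adjusted p = 0.0117 by limma's camera), with KRT20 and CEACAM6 as above and AGR2 higher by 5.31 ± 0.44. Müllerian and serous genes were called higher in 9 lines and lower in 8 with the preset correlation. KURAMOCHI came closest with an estimated one (12 of 16 members up, adjusted p = 0.0521). Without the array labelled OAW42 replicate 2 it was called (adjusted p = 0.0122 by limma), as was OVCAR3 (0.0475), both higher. PAX8, a transcription factor of the Müllerian lineage, ranged from 6.61 in Colo.720E to 12.10 in RMG1, MECOM from 4.80 in Caov3 to 11.50 in JHOC.9, and KLK6 from 5.05 in JHOM.1 to 11.48 in JHOC.7.

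Markers of other lineages were higher in a few lines. Pluripotency and germ cell genes were higher in CH1, with 8 of 11 members past the adjusted p upward (8 adjusted over the list alone; adjusted p = 2.2e-06 with an estimated correlation, limma), led by LIN28A, SOX2 (4.62 ± 0.17) and PRDM14 (4.53 ± 0.10). LIN28B was highest in A2780 (9.73) and ZFP42 in FU.OV.1 (8.43). Neural and neuroendocrine genes were higher in COLO.704 (10 of 12 members, 10 adjusted over the list alone, adjusted p = 4.04e-05) and Colo.720E (9 and 10 members, adjusted p = 0.000984). Both lines had high CHGB, chromogranin B (4.60 ± 0.13 and 4.89 ± 0.13), and the synaptic vesicle protein SYP (4.15 and 3.41). DCX, a neuronal microtubule protein, was higher by 3.80 ± 0.10 in COLO.704, and SNAP25 by 3.48 in Colo.720E. ENO2 peaked in COLO.704 (11.49) and UCHL1 in EFO.21 (12.52).

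Endothelial genes were higher in CH1 (6 members up and 3 down of 9, with the same counts adjusted over the list alone, adjusted p = 0.0332 with an estimated correlation), with the VEGF receptor KDR (4.39 ± 0.11), PECAM1 (3.61 ± 0.12) and TEK (3.20 ± 0.14). PECAM1 fell short of the fold threshold in CH1 when its probe sets were averaged (1.80). In EFO.21, 5 endothelial members passed upward (5 adjusted over the list alone, adjusted p = 0.0203), with PECAM1 as above, CDH5 (4.05) and TIE1 (2.65), although TIE1 was highest in OVCA432 (10.06). Fibroblast genes were higher in TOV112D (9 of 12 up, 9 adjusted over the list alone, adjusted p = 0.00223), with the collagen COL3A1 (6.21 ± 0.14, adjusted p = 1.37e-50 by limma), LUM (5.41) and FAP (5.13). They were also higher in A2780 (8 and 8 members, adjusted p = 0.0101), with POSTN (7.20 ± 0.22), PDGFRA (5.03) and COL3A1 (3.75). LUM reached its highest level in OV90 (10.54).

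Melanocytic, leukocyte and cancer-testis lists had no call with an estimated correlation. With the preset one the melanocytic list was higher in CH1 (2 of 5 members up and 2 down; adjusted p = 0.381 with an estimated correlation), where EDNRB (10.18) and PMEL (8.63) were highest. MITF was highest in TOV112D (10.56) and TYRP1 in A2780 (8.90). The leukocyte list was higher in EFO.21 (4 of 9 members up; adjusted p = 0.0521 with an estimated correlation), with LAPTM5 at 10.19 and ITGB2 at 10.23. LCP1 was highest in OVCAR4 (12.67) and FCER1G in OV90 (7.85). The cancer-testis list was higher in JHOC.5 (4 of 8 members up; adjusted p = 0.271 with an estimated correlation), with MAGEA4 (9.70) and MAGEA10 (9.17), and lower in 2 lines. PRAME peaked in RMG1 (11.49) and DAZL in CH1 (8.74).

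**Figure D4:**
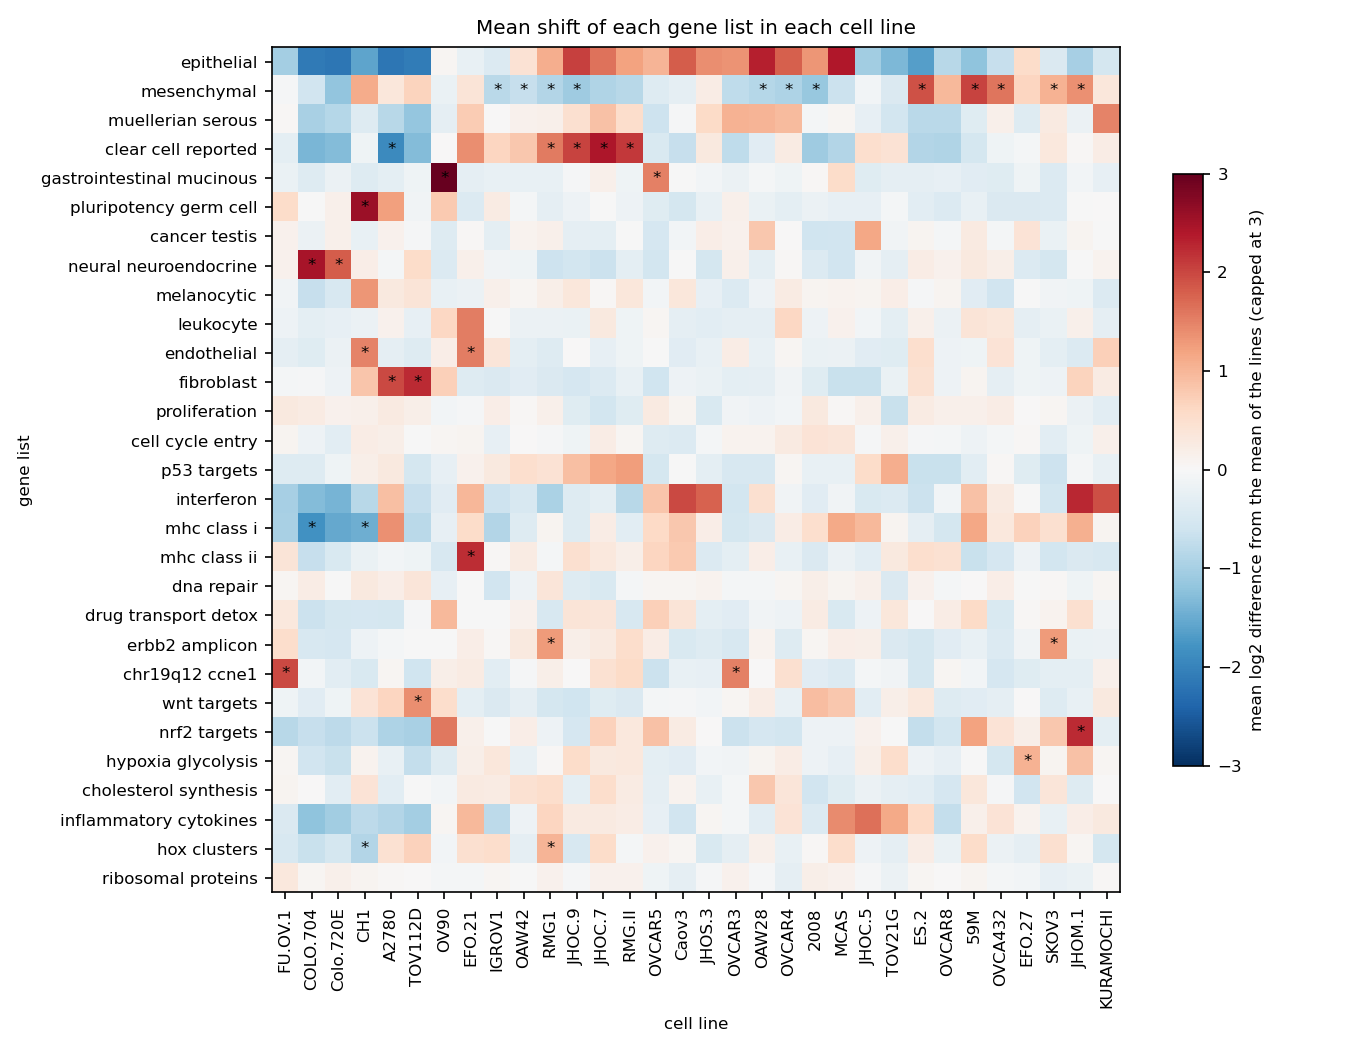
Mean log2 difference of each tested gene list (vertical axis) in each line (horizontal axis), red where higher and blue where lower, with the colour scale ending at 3. Asterisks mark the 38 combinations called with both the preset and the estimated correlation, such as the gastrointestinal and mucinous list in OV90.

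MHC class I genes were called higher in 7 lines and lower in 7 with the preset correlation. With an estimated one they were lower in CH1 (9 of 9 members, 9 adjusted over the list alone, adjusted p = 0.0265) and in COLO.704 (9 and 9 members, adjusted p = 0.0365, limma). The peptide transporter TAP1 differed by -2.31 ± 0.17 in CH1 and -2.92 ± 0.17 in COLO.704, and the immunoproteasome subunit PSMB8 by -2.82 and -2.88. PSMB9 differed by -1.72 in CH1 and TAPBP by -2.66 in COLO.704. B2M, the class I light chain, was lowest in OVCAR8 (7.18 ± 0.58). MHC class II genes were higher in EFO.21 (4 of 5 members, 4 adjusted over the list alone, adjusted p = 0.0203), with HLA-DPA1 (4.35 ± 0.18), HLA-DPB1 (3.56) and HLA-DMA (1.89). HLA-DMB was highest in FU.OV.1 (10.37).

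Interferon response genes had an estimated correlation of 0.453 between members, taken from the spread between repeats of a line. With the preset correlation they were higher in 8 lines, among them JHOM.1 (19 of 19 members up; adjusted p = 0.0884 with an estimated correlation), Caov3 (18 up; 0.192 as that adjusted p), KURAMOCHI (16 up; 0.143 as that adjusted p) and JHOS.3 (17 up; 0.199 as that adjusted p), and lower in 9. No line kept the interferon call, higher or lower, with an estimated correlation. IFI44 ranged from 3.20 in Colo.720E to 9.84 in 59M, IFIT1 from 4.69 in JHOC.9 to 11.30 in A2780, IFI44L from 4.17 in CH1 to 10.61 ± 1.35 in KURAMOCHI, and the RNA sensor IFIH1 from 4.55 in COLO.704 to 10.93 in TOV112D. Inflammatory cytokine genes were called higher in 4 lines and lower in 3 with the preset correlation, and in none with an estimated one. The adjusted p with an estimated correlation was 0.1 in JHOC.5, where 10 of 15 members were up, 0.192 in MCAS and 0.275 in TOV21G. IL6 was highest in TOV21G (11.31), IL1A in MCAS (9.83), CCL20 in OV90 (10.47) and CXCL1 in EFO.21 (12.35).

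The lists of genes next to ERBB2 and next to CCNE1 were higher in a few lines. The receptor tyrosine kinase gene ERBB2 was at 12.67 ± 0.15 in SKOV3 (n = 4), 13.9-fold above the other lines, and all 9 members of its list passed upward there (9 adjusted over the list alone; adjusted p = 0.000158 with an estimated correlation), among them PGAP3 (2.24 ± 0.10) and STARD3 (2.06 ± 0.08). STARD3 fell to 1.96 without SKOV3 replicate 4. RMG1 also had all 9 members higher (9 adjusted over the list alone, adjusted p = 9.35e-06), with GRB7 (2.27 ± 0.13), ORMDL3 (1.71) and PSMD3 (1.59). ERBB2 was lowest in ES.2 (6.15). Neighbours of CCNE1, the cyclin E gene, were higher in FU.OV.1 (5 of 6 members, 5 adjusted over the list alone, adjusted p = 8.74e-05), with PLEKHF1 (3.27 ± 0.18), POP4 (2.67) and CCNE1 itself (2.29 ± 0.13). They were also higher in OVCAR3 (5 and 5 members, adjusted p = 0.000291), with POP4 (2.48), PLEKHF1 (2.25) and URI1 (1.64). Of the CDKN2A group, described gene by gene, all 3 members were lowest in JHOM.1: MTAP at 4.89 ± 0.20, the cell cycle inhibitor CDKN2A at 5.96 ± 0.30 and CDKN2B at 6.64 ± 0.23. MTAP was at 5.11 in OVCAR5 (n = 2), and its mean over the remaining 30 lines was 8.27.

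Among signalling and metabolic programmes, NRF2 targets were higher in JHOM.1, where all 14 measured members passed upward (14 adjusted over the list alone; adjusted p = 0.00265 with an estimated correlation, limma). The leading members there were the aldo-keto reductases AKR1B10 (5.27 ± 0.26), AKR1C1 (4.96 ± 0.31) and AKR1C3 (4.51 ± 0.26), and ME1 peaked in the same line (11.83). Wnt targets were higher in TOV112D (9 of 13 up and 2 down, the same counts adjusted over the list alone, adjusted p = 0.0203), with TNFRSF19 (4.70 ± 0.13), LEF1 (4.48 ± 0.18) and AXIN2, a feedback inhibitor of the pathway (4.24 ± 0.10). Hypoxia and glycolysis genes were higher in EFO.27 (12 of 15 members, 12 adjusted over the list alone, adjusted p = 0.0203), with ALDOC (3.19 ± 0.20), BNIP3 (2.34) and PFKFB4 (1.93). PFKFB3 peaked in TOV21G (10.89) and the glucose transporter SLC2A1 in OAW28 (12.87). HOX genes were higher in RMG1 (10 up and 3 down of 15, the same counts adjusted over the list alone, adjusted p = 0.011), with HOXB2 (2.81), HOXB6 (2.45) and HOXD10 (2.43). They were lower in CH1 (14 of 15, 14 adjusted over the list alone, adjusted p = 0.0203), with HOXB7 (-1.82), HOXB2 (-1.72) and HOXB6 (-1.71). HOXC10 was highest in TOV112D (9.73) and HOXA2 in JHOS.3 (8.36).

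Targets of p53 were called higher in 6 lines and lower in 6 with the preset correlation and in none with an estimated one. The adjusted p with an estimated correlation was 0.193 in JHOC.7 (16 of 19 members up), 0.201 in RMG.II (14 up) and 0.205 in TOV21G (13 up). GDF15 peaked in RMG.II (12.11), TP53INP1 in JHOC.7 (10.58), the death receptor FAS in TOV21G (11.06) and TNFRSF10B in JHOC.5 (11.18). DNA repair genes were called lower in 3 lines, with an adjusted p of 0.283 in IGROV1, 0.39 in JHOC.7 and 0.423 in JHOC.9 under an estimated correlation. Of the 4 members with the widest ranges, FANCF was lowest in 2008 (4.84 ± 0.17) and the mismatch repair gene MSH6 in IGROV1 (6.38 ± 0.19). ATM was lowest in Caov3 (7.23 ± 0.45) and BRIP1 in OVCAR5 (7.49 ± 0.12, n = 2). The ranges of ATM (2.91) and BRIP1 (2.63) were narrower than those of FANCF (4.16) and MSH6 (3.78). Their lowest means stayed above the median of all values. Cell cycle entry genes were called lower only in OVCAR5 (11 of 19 down; adjusted p = 0.102 with an estimated correlation). RB1 was at 3.97 ± 0.77 in Caov3 against a highest level of 10.89 in 59M, CCND2 ranged from 5.19 in Caov3 to 13.36 in A2780, CDK6 from 4.33 in IGROV1 to 10.76 in OVCA432, and CCND1 from 6.79 in Colo.720E to 11.87 in JHOM.1.

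Drug transport and detoxification genes were called higher in 5 lines and lower in 2 with the preset correlation. The adjusted p with an estimated correlation was 0.0992 in OVCAR5 (10 of 20 up), 0.153 in OV90 (11 up), 0.201 in 59M, 0.363 in JHOM.1 and 0.375 in JHOC.9, and 0.54 and 0.57 in RMG1 and RMG.II, where the list was lower. The export pump ABCC2 was highest in OV90 (11.16). Cholesterol synthesis genes were called higher in 3 lines and lower in 2, and OAW28 had the smallest adjusted p with an estimated correlation among them, 0.363 (10 of 11 up). SC5D ranged from 5.79 in OVCAR8 to 11.38 in SKOV3, INSIG1 from 5.85 in JHOC.5 to 10.71 in RMG1, DHCR7 from 9.25 in JHOM.1 to 12.52 in ES.2 and STARD4 from 6.56 in MCAS to 9.82 in TOV112D.

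Proliferation and ribosomal protein genes varied least. The median range of line means was 1.73 for proliferation genes and 1.16 for ribosomal proteins, and 5 of 20 and 0 of 17 members were called across the panel, although all passed the adjusted p. Proliferation genes were called lower in TOV21G, JHOC.7 and JHOS.3 with the preset correlation (adjusted p = 0.514, 0.639 and 0.725 with an estimated one). MCM3 peaked in FU.OV.1 (11.70), FOXM1 in OVCA432 (11.15) and BUB1 in OVCAR8 (11.62). TOP2A was lowest in TOV21G (9.80 ± 1.35), and its range across lines, 2.07, was 1.68 without TOV21G replicate 2 and 1.98 after quantile normalization, so that its call was lost in both settings. Ribosomal proteins were called higher in FU.OV.1 and lower in OVCAR4 and SKOV3 (adjusted p = 0.476, 0.507 and 0.429 with an estimated correlation). The widest ranges were those of RPS23 (1.95), RPS13, RPL32 (1.88) and RPS16 (1.40).

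Pairs of lines differed by a median of 730 genes. The closest pair was COLO.704 and Colo.720E, with 135 genes called and a mean correlation of 0.953 between their arrays, and these were the lines that shared IMPG2, CHGB and SYP. JHOC.7 and JHOC.9 followed with 201 genes, and RXFP1, CALB1 and SPP1 were high in both. OAW28 and OAW42 differed by 274 genes with all arrays and by 685 without the array labelled OAW42 replicate 2. The farthest pair was COLO.704 and MCAS, with 1482 genes. The median pair differed by 2427 genes when a difference of 1 sufficed.

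Among the fixed gene pairs, 18 correlations across lines were computed, and 6 passed the adjusted permutation p for Pearson's r. The p53 targets MDM2 and CDKN1A correlated over the 32 lines (r = 0.770, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 9e-05; rho = 0.688, permutation p = 2e-05), and so did TAP1 and PSMB9 (r = 0.770, permutation p = 1e-05, again the smallest possible, adjusted p = 9e-05; rho = 0.814, permutation p = 1e-05). Without the 2 lines farthest in the x gene, r was 0.694 and 0.711. ERBB2 and GRB7 correlated at r = 0.577 (permutation p = 0.00023, adjusted p = 0.00138; rho = 0.669, permutation p = 2e-05), and at 0.643 without SKOV3 and ES.2. In the 21 lines with high PAX8 (cluster mean 10.79), PAX8 and SOX17 correlated at r = 0.636 (permutation p = 0.00193, adjusted p = 0.00869; rho = 0.539, permutation p = 0.0127; r = 0.581 without OVCAR8 and RMG1). In 28 lines with high KRT18, KRT8 and KRT18 correlated at r = 0.510 (permutation p = 0.00745, adjusted p = 0.0268; rho = 0.805, permutation p = 1e-05; r = 0.606 without ES.2 and TOV21G), and the remaining 4 lines were too few for a test. EPCAM and GRHL2 correlated in the 12 lines with high GRHL2 (r = 0.688, permutation p = 0.0105, adjusted p = 0.0316; rho = 0.699, permutation p = 0.0139), but r was 0.474 (permutation p = 0.17) without OAW28 and JHOC.9.

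CDH1 split the panel into 17 lines with low levels (cluster mean 5.68) and 15 with high levels (10.65), and no pooled r is given for it. Within the low and high clusters its r with VIM was -0.135 (permutation p = 0.631; rho = -0.468, permutation p = 0.0594) and -0.308 (permutation p = 0.26; rho = -0.214, permutation p = 0.441), and its r with ZEB1, a repressor of CDH1, was -0.190 (permutation p = 0.468; rho = -0.387, permutation p = 0.124) and -0.472 (permutation p = 0.0765; rho = -0.457, permutation p = 0.0903). None passed the adjusted p with all arrays. CDH1 and ZEB1 at high CDH1 did pass on replicate 1 only (r = -0.678, adjusted permutation p = 0.0139) and without OVCAR5 replicate 2 (r = -0.637, adjusted permutation p = 0.0283). PAX8 and WT1, PAX8 and SOX17 in the 11 lines with low PAX8, EPCAM and GRHL2 in the 20 lines with low GRHL2, CDKN2A and MTAP, RB1 and CDKN2A, and CCNE1 and URI1 did not pass either. Their r lay between -0.399 for PAX8 and WT1 at low PAX8 (permutation p = 0.189; rho = -0.464, permutation p = 0.157) and 0.468 for PAX8 and SOX17 at low PAX8 (permutation p = 0.124; rho = 0.473, permutation p = 0.147). CCNE1 and URI1 were tested only in the 30 lines left without FU.OV.1 and OVCAR3, the high-URI1 cluster. Likewise, CDKN2A and MTAP were tested only in the 30 lines left without JHOM.1 and OVCAR5, the low-MTAP cluster. Those clusters were too small for a test, so these r do not cover the lines with the extreme levels.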

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

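The tests on the OAW42 array and on the COLO pair were chosen after those results were seen; the regroupings of the arrays, the outlier tests and the tests of neighbouring genes were set before.

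In the lines with 4 arrays, 112 values were tested for 1 array far from the other 3, and 5 stood apart where chance gives about 1 in 20, or 5.6. In JHOS.3, the mean score of MHC class II genes was -0.29 on replicate 2, against -0.45 on average in the other arrays. In OV90, the score of ERBB2 and its neighbours was -0.18 on replicate 1 (0.03 on average in the others) and that of cholesterol synthesis genes was 0.0839 on replicate 2 (-0.12 in the others). In SKOV3, the spread of all values on replicate 1 was 2.49 against 2.51, and the receptor kinase gene AXL was at 12.17 on replicate 2 against 11.75. The number of such values did not exceed chance.

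The array labelled OAW42 replicate 2 carried the OAW28 profile. A swap within the pair would need an OAW28 array out of place, and 0 were. A mixture of both RNAs would raise the 55 genes that are at least 4 log2 units brighter in OAW42 replicates 1 and 3, but their median excess over OAW28 was 0.0371 (SD 0.0306), and the weight of those replicates in its profile was 0.0108. A single mislabelled array remains: its lowest correlation with OAW28 was 0.989, above the 0.961 that the other repeat pairs reached at the lowest, which is consistent with OAW28 RNA under an OAW42 name. No biological explanation was tested, and the point in the work at which the name might have changed cannot be read from the values.

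COLO.704 and Colo.720E were the closest pair, and both had high IMPG2 and the high neuroendocrine genes CHGB and SYP. A mislabelled array within the pair was argued against, since 0 of their arrays matched another line best. A single culture under both names was argued against as well, since the highest correlation between them was 0.957 and the lowest between repeats of either was 0.975. Shared handling of same-numbered arrays was left open: their residuals correlated at 0.124, 0.234 and 0.0515, all above 0 but not all above 0.1. The labels give no relation between the lines, so no biological explanation was tested.

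Neighbouring genes moved together in every line. Windows of 15 genes gave 412 runs (189 higher and 223 lower) past the shuffled gene orders, some of which overlap and share genes, and 32 lines had at least 1 where chance would give 1.6. Families of like-named genes side by side were argued against as the whole source, since 31 lines kept a run without such neighbours, although the CH1 run of SNORD116 genes on chromosome 15 was not kept. Regional copy number change may account for such runs, as 32 lines showed them, but DNA was not measured and shared regulation of neighbours would give the same value. Examples are the TOV112D run on chromosome 2 with GCG, FAP and IFIH1, the OV90 run on chromosome 22 with SERPIND1 and SNAP29, and the FU.OV.1 run on chromosome 19 with CCNE1, POP4 and URI1.

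Chance as the source of the calls was tested by drawing 99 other groupings of the 98 arrays into groups of the same sizes. Only the real grouping, 1 of 100, reached 6678 panel genes, where the highest other grouping gave 71. The median line pair had 730 genes against 0 at the highest. For gene lists the real value was 224 against 180 with the preset correlation, which shows how freely that setting calls lists in groupings without meaning, and 38 against 4 with an estimated correlation. In each of the 31 lines with at least 3 arrays the real count of called genes was above every other grouping. By ratio, the margins were narrowest in TOV21G (286 against 242), OAW42 (106 against 87) and JHOC.9 (344 against 242). No regrouping reached the real counts for the panel, the lists or these lines, so the labels group like arrays together. Mixed groups widen the spread within groups and lower the counts, however, so lower counts were largely built into the test. It cannot exclude chance as the source of single calls. The gaps do not measure how far the lines differ, and the pair count of 0 adds no support.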

How the results depend on the processing

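Leaving out the array labelled OAW42 replicate 2 from all results, leaving each array in turn out of the gene pairs, and leaving a close partner line out were tests chosen after the data were seen. Of 1605 values of the main results under other settings, 1594 kept their direction and side of the threshold, or stayed within 1.5 times for counts. Most of these values come from leaving out 1 of 98 arrays, which can hardly move a count over the whole panel by 1.5 times. The share kept is thus largely built in and does not measure robustness to the processing. The panel gave 13862 genes by adjusted p alone and 12470 with a range of 1, the median line pair 2427 genes with a difference of 1, and the lists 38 calls with an estimated correlation, or 47 with it and without that array, where 35 of the 38 were kept and 12 were gained, 6 of them for epithelial genes. All but the last follow from the threshold or the stricter test. The median SD between repeats was 0.20 without that array and 0.21 with it. The median r between lines was 0.949 over all probe sets, dim ones included. With 1 array left out, arrays matching another line best ranged from 0 to 5, calls in OAW42 from 92 to 286 (180 higher and 106 lower without replicate 2) and the OAW28 and OAW42 pair from 119 (without replicate 1; 140 without replicate 3) to 685. At the fold threshold of 2, other lines' counts stayed within 1.5 times, with ratios of 0.826 to 1.08 over the settings that kept all arrays. No smaller fold was tried for them, and by the adjusted p alone they were far larger (5549 against 214 in EFO.27 and 7588 against 212 in SKOV3). For OVCAR5 this left 1 array, assumed to vary like the other lines. With the close partner line left out, COLO.704 had 775 calls, Colo.720E 673, JHOC.7 434 and JHOC.9 367. Gene pairs that did not pass changed sign in the reported r: CDH1 with VIM at low CDH1 (0.0134, replicate 1 only) and at high CDH1 (0.0659, without 2 lines), EPCAM with GRHL2 at low GRHL2 (-0.0483, replicate 1 only, and -0.0672 without OAW42 replicate 2, against 0.315 without its replicate 1), and RB1 with CDKN2A at high CDKN2A (-0.175, without 2 lines). CDH1 with ZEB1 at high CDH1 passed on replicate 1 only and without OVCAR5 replicate 2 (r = -0.678 and -0.637). The cause was not tested. Of 231 named differences, 226 kept their call in the settings run for their line. The 38 list shifts kept theirs by the preset test in such settings, although 3 of them were lost with the estimated correlation and without the array labelled OAW42 replicate 2. PECAM1 in CH1 (1.80), GLMP (1.82 and 1.99) and SNAI2 (-1.89) in OAW42, FN1 in OVCAR4 (-1.88) and STARD3 in SKOV3 (1.96) missed the fold threshold in some setting. The KRT8 and KRT18 correlation was lost on replicate 2 only (r = 0.456, adjusted permutation p = 0.0582), and the EPCAM and GRHL2 one there (0.620) and without OVCAR5 replicate 1 (0.628).

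The labels do not say what a replicate number stands for, and the numbers were not taken to pair the arrays. The correlation of residuals between same-numbered arrays of different lines was as low as -0.374. That is the lowest of many pairs, with the array labelled OAW42 replicate 2 included, so it cannot argue against shared handling. Same-numbered arrays still resembled each other more than chance gives: the median correlation was 0.0606, against -0.0277 for other numbers, and 53 of 98 arrays matched their own number best, where 1000 shuffles of the numbers within lines gave a median of 30 and at most 48 (permutation p = 0.000999, the smallest possible). This is a hint from the data that arrays of 1 number shared some handling. With a replicate block the panel gave 6686 genes, the median line 292.5, the median pair 730 and the lists 224. All 40 counts compared stayed within 1.5 times of those without the block, which does not show that each single call was kept. The planned exclusion of cross-hybridising probe sets was not run, because the probe set names carry no such suffix. Arrays hold no depth, and dim genes are limited by the background: 3733 genes were not tested.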

Other observations

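The members named for OAW42 from its replicates 1 and 3 were chosen after their values were seen, as were the neighbouring genes named here.

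Without the array labelled replicate 2, OAW42 (n = 2) was led by RXFP1 (6.46 ± 0.22), the pluripotency-associated gene DPPA2 (6.05 ± 0.16) and TCL1B (5.94 ± 0.15), and TCL1B stood 5.07 above the next line. NNT differed by -4.87 ± 0.16 (adjusted p = 6.25e-40 by limma). In OV90, albumin, ALB, and alpha-fetoprotein, AFP, were among the top genes of 1 run on chromosome 4, where 10 of 15 genes were on the higher side, and the fibrinogen genes FGA, FGB and FGG of another, where 8 of 18 were, so that a few genes carried the mean of each. Protocadherin genes on chromosome 5, among them PCDHB8, PCDHB6 and PCDHB10, formed a run of 34 genes in EFO.21, 31 of them on the higher side. Keratinocyte genes SPRR1B, SPRR3 and S100A14 formed a run on chromosome 1 in MCAS, and metallothionein genes MT1G, MT1E and MT2A a run on chromosome 16 in Caov3, and neither was kept without neighbours of like name.

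The nearest neighbours of some of the strongest drops fell far too, and those of others fell less. UBE2G1 in SKOV3 (-6.26) had ANKFY1 (-3.88) on 1 side and SPNS3 (-0.15) on the other, C4orf46 in Caov3 had ETFDH (-4.09) on 1 side and on the other RXFP1, which only a few lines expressed, GOLIM4 in OVCAR8 had MECOM (-3.83) and SERPINI1 (-1.07), and S100A10 in Colo.720E had S100A11 (-6.35) and THEM4 (0.51). LDHB in MCAS had SPX (-0.66) and KCNJ8 (-0.15), and MAP4K5 in JHOS.3 had CDKL1 (-0.23) and ATL1 (-1.25). Both drops lay in a longer run past the shuffled gene orders, with 16 of 17 genes on the lower side in MCAS and 15 of 26 in JHOS.3. The dropped gene counts in the mean of each window that holds it, so these runs are not separate evidence of a shift around it. In JHOS.3 a few genes could carry the run.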
